A study of Mus musculus with 38 samples.

How the data were processed

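RNA was sequenced from whole bone marrow and from sorted marrow cells of female C57BL/6 mice that were left untreated or given zoledronic acid (ZA), G-CSF, or both. ZA was injected at 100 µg per kg, and G-CSF at 50 µg per kg in 3 daily doses that began 2 days after ZA, per the labels' protocols. The sorted cells lacked lineage markers (CD3, Ly-6G/Ly-6C, CD11b, CD45R and TER119) and carried CD115, and the labels call them osteoclast precursors. The labels' protocols also name nude mice in other experiments of the study. Libraries were made with an NEB Ultra RNA kit and sequenced on a HiSeq 2000, per the labels, which do not state whether the kit kept strand. Reads from a gene and an antisense partner are therefore treated as uncertain.

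The deposited tables give estimated counts and TPM per gene under Ensembl mouse gene identifiers. The submitters' processing notes name Salmon (no version), DESeq2 1.16.1 and the mouse build mm10. The estimated counts deposited by the authors are not whole numbers, and each equals the TPM times a length per gene that is the same in every library times a factor per library. The TPM deposited by the authors sum to the same total in each library. The authors' counts carry no scaling between libraries. The annotation release is not stated, and how Salmon split reads among near-identical gene copies cannot be seen, so values of such copies are uncertain.

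One pair of tables holds 9 whole marrow libraries (untreated 2, G-CSF 3, ZA 2, combined 2) with 47729 genes. The other holds 29 libraries with 46679 genes: 8 precursor and 3 whole marrow libraries in sequencing run 1, and 15 precursor and 3 whole marrow libraries in run 2. The labels put 17 precursor libraries in the final comparison (untreated 2, G-CSF 5, ZA 5, combined 5), and every group had libraries of both runs. The labels number biological replicates but do not say that these are separate animals, so p-values measure the spread between these samples. Gene symbols, types and coordinates came from GENCODE vM21 on GRCm38, the assembly that mm10 names; 98.9% of the whole marrow table's identifiers and 99.0% of the precursor table's matched.

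Total estimated counts (M for mega) ran from 6.24 to 16.2 M in the 9 whole marrow libraries (median 8.44) and from 6.65 to 37.1 M in the 29 libraries of the precursor table (median 17.1). The 17 final precursor libraries had 6.65 to 33.2 M (median 24.5). A count of 0 in a library allows up to 3 counts, which is 0.186 to 0.481 CPM (counts scaled by library total) in whole marrow and 0.0904 to 0.451 CPM in the final precursor libraries. Intervals and floors cover counting error alone.

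Counts were rounded and tested with edgeR 4.0.16 (quasi-likelihood test, robust) in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Unless another test is named, adjusted p values of genes come from this edgeR test. Whole marrow was fitted with 4 groups in 1 model (14737 genes tested). The final precursor libraries were fitted with 4 groups and a run term (18954 genes tested). Each treatment was compared with untreated, the treatments were compared with each other, and an interaction term asked whether the combination departed from the sum of the separate log2 changes. Precursors were compared with whole marrow among run 2 libraries of 3 treatments with treatment as a term (16136 genes), and with run 1 libraries of the same treatments as another setting fixed beforehand (16185 genes). Run 2 was compared with run 1 in the 9 samples sequenced in both, with the sample as a block (14175 genes). Log2 fold changes are given ± the standard error, computed as the size of the log2 fold change over the square root of the F statistic. Levels are TMM-scaled CPM as mean ± SD. A fold against a group at 0 in every library is a lower bound against 3 counts over the group, and a ratio to a group with 1 to 3 counts is given with its 95% exact Poisson interval.

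Gene lists (22, of cell types and pathways) were tested with camera in limma 3.58.1 with a preset correlation of 0.01 on voom values, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. Adjusted p values of lists come from camera with the preset correlation unless an estimated correlation is named. List medians are medians of log2 fold changes over the measured members, and counts of members are given over all genes tested and adjusted over the list alone.

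The named genes followed a rule. For each treatment against untreated, and for the combination against G-CSF, the 8 rising and 8 falling genes with the largest log2 change were eligible. They had to pass the test, average at least 5 CPM, and lie on the called side of the comparison group's mean in every treated library; predicted gene models and immunoglobulin and T cell receptor segments were left out. Up to 4 members of each list with the smallest p and 13 fixed genes were added. Where fewer than 3 passed, the 3 smallest p values were named and are said not to pass. For the other comparisons 3 genes per direction were eligible. Some names were left out for length, and some single genes are not reported here.

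The tests, groups, lists, naming rule and most alternatives were fixed before the data were examined. Fixed beforehand as other settings were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, limma-trend on log2(TPM + 1) for genes with a mean TPM of at least 1, each library left out, the replicate number as a block, and a fit of the compared groups alone. For precursors they were also no run term, run 2 alone, both runs summed per replicate, and all libraries in voom with a random block. Chosen after seeing the data were run 1 alone in the treatment comparisons of precursors, like libraries counted once, leaving out libraries with a marrow profile, both of these together, the run comparison without the samples labelled untreated 2 and G-CSF 2, and the gene lists in such subsets.

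Similarity of libraries was measured after thinning to 6 M counts, over genes with at least 40 summed counts, as the spread of the difference relative to counting noise (1 is counting noise alone). A bound of 2.5 for the same library sequenced again was set after the values were seen, in a gap between 2.42 and 3.15. Genes called on or off between sets of libraries had at least 1 TPM in every library of one set and at most 0.1 TPM in every library of the other.

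The tests were tried on simulated counts drawn from the real means and library sizes, with 200 genes changed. For G-CSF against untreated marrow (14347 genes), edgeR recovered 23.9% of the genes changed 2-fold, 86.6% of those changed 4-fold and 90.9% of those changed 8-fold, with 9 false calls among 143. DESeq2 recovered 34.3%, 95.5% and 97.0% with 26 false calls among 177. For ZA against untreated marrow (14331 genes) edgeR recovered 8.96%, 77.6% and 83.3%. For G-CSF against untreated precursors (18373 genes) it recovered 22.4%, 56.7% and 78.8%, with 2 false calls among 107. For the combination against G-CSF in run 1 precursors (17986 genes) it recovered 59.7%, 82.1% and 86.4%, with 19 false calls among 171. The simulated libraries were drawn independently, so the rates for pooled precursors do not allow for like libraries or marrow profiles. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for library similarity and plots. No column of values per sample was left unused.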

Results

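Gene expression was measured by RNA sequencing in mouse bone marrow after zoledronic acid (ZA), after G-CSF, and after both. ZA is a bisphosphonate that binds bone and blocks farnesyl diphosphate synthase in osteoclasts. G-CSF is a cytokine that drives neutrophil production and releases stem cells from marrow. Whole marrow gave 9 libraries: 2 untreated, 3 with G-CSF, 2 with ZA and 2 with both. Sorted osteoclast precursors gave 17 libraries in the final comparison: 2 untreated and 5 in each treatment. Whole marrow libraries held 6.24 to 16.2 M estimated counts and the final precursor libraries 6.65 to 33.2 M. The design asks for pairwise comparisons of the treatments. Levels below are CPM as mean ± SD with these numbers of replicates.

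In whole marrow, G-CSF was set against no treatment to ask what differs under the cytokine alone. Genes that differ between mouse strains also divided both groups given G-CSF from the other groups, as described below. Differences in any marrow comparison across this division may therefore hold genetic background as well as treatment. Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970, mm10), a surface protein of inflammatory monocytes, fell. Its level went from 489 ± 46.3 CPM in untreated marrow (n = 2) to 56.3 ± 18.6 with G-CSF (n = 3). This was a log2 change of −3.12 ± 0.28 (adjusted p = 0.00021). Ly6c2 has near-identical neighbours, so its level is uncertain. The fractalkine receptor Cx3cr1 fell by 2.36 ± 0.25 on the log2 scale (adjusted p = 0.000489), and Irf8, a transcription factor of monocyte fate, fell by 1.40 ± 0.23 (adjusted p = 0.00528). The neutrophil precursor gene Mpo, myeloperoxidase (ENSMUSG00000009350, chromosome 11, 87793581 to 87804413), was at 1750 ± 290 against 851 ± 177 CPM, a rise that was not called without untreated replicate 2 (adjusted p = 0.0804). The interferon-induced antiviral gene Rsad2 (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452) fell from 1082 ± 199 to 225 ± 27.9 CPM. For each gene called here and below in this comparison, the 3 G-CSF libraries all lay on the same side of both untreated libraries.

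The edgeR test called 1746 of 14737 genes, 727 higher and 1019 lower with G-CSF. Without untreated replicate 2 it called 836. Without G-CSF replicate 1 it called 1009 and without G-CSF replicate 2 it called 1003. On the TPM scale 1974 genes were higher and 116 lower. The median log2 change of all genes there was 0.64 against 0.01 in the edgeR fit. Where a list that was called lower had a positive median there, the median relative to all genes is also given. The other medians on that scale are to be read against 0.64. Untreated replicate 1 had 39.1% of its TPM in small RNA genes, against 6.46% to 12.3% in the other 8 libraries.

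Of the 10 neutrophil primary granule genes 6 rose, also 6 adjusted over the list alone, with a median log2 change of 0.78 (adjusted p = 3.7e-05, and adjusted p = 0.408 with an estimated correlation). Proteinase 3, Prtn3, rose by 1.02 ± 0.18 (adjusted p = 0.00869) and Mpo by 1.04 ± 0.19 (adjusted p = 0.00966). Mpo was not called without untreated replicate 2 (0.84, adjusted p = 0.0804). Of the 15 secondary and tertiary granule genes 1 rose and 2 fell (3 and 2 adjusted over the list alone; median −0.20, but 0.66 on the TPM scale; adjusted p = 0.848). Ly6g, the neutrophil surface antigen, rose by 1.12 ± 0.15 (adjusted p = 0.00232). The integrin Itgb2l (ENSMUSG00000000157, chromosome 16, 96422288 to 96443619) fell by 3.25 ± 0.25 (adjusted p = 7.8e-05), and the chitinase-like protein Chil3 fell by 1.87 ± 0.20 (adjusted p = 0.000489). In the mature neutrophil list 3 of 12 fell (4 adjusted over the list alone; median −0.11, but 0.74 on the TPM scale; adjusted p = 0.230). The G-CSF receptor Csf3r had a log2 change of 0.00 ± 0.21 (adjusted p = 1.00) and lactoferrin, Ltf, 0.36 ± 0.16 (adjusted p = 0.170).

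Of the 18 monocyte and macrophage genes 8 were lower and, adjusted over the list alone, 12 were lower and 1 higher. The list fell (median −0.59, but 0.23 on the TPM scale, −0.41 relative to all genes there; adjusted p = 3.5e-06, and adjusted p = 0.370 with an estimated correlation). The M-CSF receptor Csf1r fell by 0.63 ± 0.16 (adjusted p = 0.0313) and was 0.19 on the TPM scale, under the median of all genes there. Csf1r was not called without untreated replicate 2 (adjusted p = 0.205), G-CSF replicate 1 (0.0914), 2 (0.0884) or 3 (0.0541), or combined replicate 1 (0.0551) or 3 (0.0540). The dendritic cell list had 6 of 14 lower and 7 adjusted over the list alone. It fell as well (median −0.74, but 0.26 on the TPM scale, −0.38 relative to all genes; adjusted p = 0.00053, and adjusted p = 0.408 with an estimated correlation). Its member H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305867 to 34316674), a class II antigen-presentation gene with near-identical copies, was at 143 ± 19.6 CPM in untreated and 5.73 ± 1.39 in G-CSF marrow (−4.66 ± 0.26, adjusted p = 1.4e-05). Ly6d fell by 2.03 ± 0.18 (adjusted p = 0.000213). In the osteoclast list 1 of 16 rose and 1 fell, the same counts adjusted over the list alone (median 0.09, adjusted p = 0.867). Cathepsin K, Ctsk, the bone-resorbing protease, rose by 2.40 ± 0.46 (adjusted p = 0.0110), though not without untreated replicate 2 (2.20, adjusted p = 0.0893). The receptor Trem2 fell by 1.93 ± 0.28 (adjusted p = 0.00305). The RANK receptor Tnfrsf11a (0.10 ± 0.60, adjusted p = 0.930), the osteoclast transcription factor Nfatc1 (−0.29 ± 0.19, adjusted p = 0.348) and Acp5, the osteoclast acid phosphatase (0.02 ± 0.23, adjusted p = 0.972), were not called.

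In the erythroid list 7 of 15 were lower and, adjusted over the list alone, 10 lower and 2 higher. It fell (median −0.68, but 0.16 on the TPM scale, −0.48 relative to all genes; adjusted p = 0.00013, and adjusted p = 0.408 with an estimated correlation). The red cell anion exchanger Slc4a1 fell by 2.83 ± 0.34 (adjusted p = 0.00141). The globin Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096), which has a near-identical copy, fell by 1.42 ± 0.24 (adjusted p = 0.00628). All 12 megakaryocyte and platelet genes had positive changes, with 1 called and 8 adjusted over the list alone. The list rose (median 2.19, adjusted p = 3.5e-06, and adjusted p = 0.449 with an estimated correlation). The stromal niche list rose, with 2 of 19 called and 2 adjusted over the list alone (median 1.02, adjusted p = 0.00186, and adjusted p = 0.638 with an estimated correlation). Its members Cxcl12, which holds stem cells in the niche, and Spp1 had log2 changes of 1.66 ± 0.64 (adjusted p = 0.137) and 0.87 ± 0.35 (adjusted p = 0.137). Cxcl12 was called without ZA replicate 2 (adjusted p = 0.00137) or ZA replicate 3 (0.0014). The endothelial list rose with no member called over all genes (median 0.79, adjusted p = 0.0290, and adjusted p = 0.638 with an estimated correlation).

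The interferon response list fell, with 8 of 17 lower and 10 adjusted over the list alone (median −1.13, adjusted p = 3.3e-05, and adjusted p = 0.408 with an estimated correlation). Rsad2 fell by 2.27 ± 0.19 (adjusted p = 0.000172). The interferon regulator Irf7 fell by 1.90 ± 0.24 (adjusted p = 0.00137) and the ubiquitin-like Isg15 by 2.25 ± 0.38 (adjusted p = 0.00772). Of the 13 mitochondrially encoded genes 2 rose and 5 fell, and 2 and 6 adjusted over the list alone. Their list fell (median −0.60, but 0.34 on the TPM scale, −0.30 relative to all genes; adjusted p = 0.0155, and adjusted p = 0.638 with an estimated correlation). The respiratory chain genes mt-Nd5 and mt-Co1 fell by 1.38 ± 0.18 (adjusted p = 0.0019) and 0.97 ± 0.17 (adjusted p = 0.0068). The plasma cell list fell, with 1 of 6 lower and 2 adjusted over the list alone (median −0.53, but 0.35 on the TPM scale, −0.29 relative to all genes; adjusted p = 0.0228, and adjusted p = 0.408 with an estimated correlation).

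The remaining lists did not pass. B lineage had 3 of 16 lower, also 3 adjusted over the list alone (median −0.17, but 0.57 on the TPM scale; adjusted p = 0.0904). The B cell receptor inhibitor Cd22 fell by 2.38 ± 0.29 (adjusted p = 0.00117). In the T and NK cell list 3 rose and 3 fell of 16, and 4 and 4 adjusted over the list alone. Its median of −0.01 (0.57 on the TPM scale) and mean of −0.29 were negative while the test pointed up (adjusted p = 0.942). The T cell receptor subunit Cd3d rose by 2.01 ± 0.22 (adjusted p = 0.0006) and the protease Gzma by 2.42 ± 0.31 (adjusted p = 0.00148). Cd8a fell by 4.25 ± 0.62 (adjusted p = 0.00327). Cd3e was at 5.04 CPM in untreated and 0.0634 in G-CSF marrow. Its ratio, taken against the rounded counts summed over the G-CSF group rather than these mean levels, was 93.7 (95% interval 25.9 to 773; adjusted p = 0.00322). The stem and progenitor list had 1 of 14 higher (median 0.40, adjusted p = 0.245). The mast cell, basophil and eosinophil list had 2 of 11 lower (1 higher and 2 lower adjusted over the list alone; median −0.41, but 0.39 on the TPM scale; adjusted p = 0.123). The cell cycle list had 2 of 18 lower (median −0.03, but 0.83 on the TPM scale; adjusted p = 0.723). The inflammatory list had 2 of 9 lower (median −0.15, but 0.38 on the TPM scale; adjusted p = 0.663). In the mevalonate list, the pathway that ZA blocks, 2 of 20 rose (median 0.03, adjusted p = 0.527). Fdps (0.29 ± 0.18, adjusted p = 0.310) was not called. In the STAT3 list 2 rose and 2 fell of 11, and 3 and 3 adjusted over the list alone. The median was 0.27, the mean −0.06 and the test pointed up (adjusted p = 0.914). The transcription factor Cebpd rose by 1.08 ± 0.18 (adjusted p = 0.00645). In the immediate early list 1 of 10 fell. The median was 0.04, the mean −0.16 and the test pointed down (adjusted p = 0.848).

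The largest fold changes were of genes near 0 in the marrow of one set of groups. Eno1b (ENSMUSG00000059040, chromosome 18, 48045335 to 48048412), an enolase gene close in sequence to Eno1, was at 0 in untreated marrow and 217 ± 23.2 CPM with G-CSF, at least 784-fold higher (adjusted p = 1.4e-05). The class I gene H2-Bl was at least 300.2-fold higher (adjusted p = 7.4e-06) and the interferon-inducible Ifi202b at least 35.6-fold higher (adjusted p = 0.00244). All 3 have near-identical relatives and are uncertain. The interferon-induced GTPase Gvin1 was at least 875-fold lower (adjusted p = 0.00101) and Eps8l1, an actin regulator, at least 167-fold lower (adjusted p = 0.000134). The villin-like gene Vill fell by 8.32 ± 0.68 (adjusted p = 0.00021). Across all 9 libraries, 50 genes had at least 1 TPM in all 5 libraries of both groups given G-CSF and at most 0.1 TPM in the other 4. Another 11 showed the opposite. Of these 61, 8 were protein-coding. Genes that differ between mouse strains are among them, and genetic background cannot be told apart from treatment here. In run 1 precursors of G-CSF mice, Eno1b was at 0.423 ± 0.460 CPM (n = 3) and Vill at 59.4 ± 14.2.

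ZA alone was set against no treatment to ask what the bisphosphonate does in marrow. Aacs (ENSMUSG00000029482, chromosome 5, 125475814 to 125517410), which makes acetoacetyl-CoA for lipid synthesis, rose from 19.2 ± 2.83 to 83.5 ± 9.94 CPM (n = 2 each; 2.13 ± 0.23, adjusted p = 0.0408). The deubiquitinase Usp37 (ENSMUSG00000033364, chromosome 1, 74435511 to 74544284) fell from 78.6 ± 24.2 to 17.2 ± 0.862 CPM (−2.20 ± 0.26, adjusted p = 0.0475). The antisense gene H3f3aos, uncertain because strand was not stated, fell by 4.54 ± 0.55 (adjusted p = 0.0485). For these 3 genes both ZA libraries lay beyond both untreated libraries. The targets and markers of ZA's known site of action were not called. Fdps, the enzyme it inhibits, changed by 0.16 ± 0.19 (adjusted p = 0.820). Ctsk changed by 0.95 ± 0.48 (adjusted p = 0.558), Csf1r by −0.14 ± 0.17 (adjusted p = 0.828) and Mpo by 0.50 ± 0.21 (adjusted p = 0.502).

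Among lists, the 13 mitochondrially encoded genes all had positive changes and 10 passed adjusted over the list alone (median 0.81, adjusted p = 1.7e-16, and adjusted p = 0.375 with an estimated correlation). The mitochondrial share of TPM was 1.78% and 3.54% in untreated and 5.65% and 6.46% in ZA marrow. The 1.78% is of untreated replicate 1, whose 39.1% of TPM in small RNA genes lowers its other shares. The gene mt-Co2 changed by 1.23 ± 0.24 (adjusted p = 0.220) and mt-Nd6 by 1.10 ± 0.20 (adjusted p = 0.189). The primary granule list rose (median 0.30, adjusted p = 0.00597, and adjusted p = 0.400 with an estimated correlation). So did the secondary granule (0.19, 0.0109 and 0.400), STAT3 (0.35, 0.0268 and 0.400) and endothelial lists (0.89, 0.0277 and 0.680). The monocyte list fell (median −0.37, but 0.10 on the TPM scale, −0.22 relative to the median of all genes there, which was 0.32; adjusted p = 0.000245, and adjusted p = 0.375 with an estimated correlation). Its member F13a1 was at −0.54 ± 0.17 (adjusted p = 0.429). The dendritic list fell (median −0.28, but 0.07 on the TPM scale; adjusted p = 0.00597). So did the B lineage (−0.08, but 0.34 on the TPM scale; adjusted p = 0.0109) and plasma cell lists (−0.68, adjusted p = 0.00647). Each of these 3 had an adjusted p = 0.400 with an estimated correlation. B lineage and plasma cell had 3 members lower each adjusted over the list alone. Irf4 of the plasma cell list changed by −0.79 ± 0.20 and the cytokine Il1b by 1.20 ± 0.31 (adjusted p = 0.334 for both). No list member passed edgeR's test over all genes.

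In all, edgeR called 5 of 14737 genes in ZA marrow, 1 higher and 4 lower, with 1395 at an unadjusted p under 0.05. The DESeq2 Wald test called 53 higher and 86 lower, and edgeR 634 without the filter on low counts. With the replicate number as a block it called 0, with Aacs at an adjusted p = 0.117, Usp37 at 0.0744 and H3f3aos at 0.237. In a fit of the 2 groups alone none of these 3 was called either (0.187, 0.261 and 0.187). The other 2 called genes, the predicted gene Gm8116 and the ribosomal protein pseudogene Rps3a2, are named after their values were seen. Leaving out 1 library gave 0 to 23 calls. There were 23 without untreated replicate 2, 20 without untreated replicate 1, and 3 without either combined replicate. There were 2 without ZA replicate 2, 1 without G-CSF replicate 1, and 0 without G-CSF replicate 2 or 3 or ZA replicate 3. Aacs was not called without untreated replicate 2 (adjusted p = 0.0571), G-CSF replicate 1 (0.0552), 2 (0.0747) or 3 (0.0670), or ZA replicate 2 (0.0507) or 3 (0.0749). Usp37 was called only when no library or an untreated replicate was left out (otherwise 0.0552 to 0.178). H3f3aos was called only with all libraries or without untreated replicate 2 (otherwise 0.0507 to 0.145).

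The combination was set against no treatment. Ly6c2 was at 20.02 ± 4.10 CPM with both agents (n = 2) against 489 ± 46.3 (−4.61 ± 0.35, adjusted p = 0.000117). The neutrophil genes Itgb2l and Chil3 fell by 2.92 ± 0.29 (adjusted p = 0.000454) and 2.13 ± 0.23 (adjusted p = 0.000812). The interferon genes Rsad2, Irf7, Oas1a and Ifit1 fell by 2.497 ± 0.23, 2.55 ± 0.28, 2.88 ± 0.33 and 3.16 ± 0.38 (adjusted p = 0.000322, 0.000921, 0.00116 and 0.00161). H2-Eb1 fell by 4.95 ± 0.31 (adjusted p = 3.9e-05), Ly6d by 2.84 ± 0.22 (adjusted p = 0.000118) and Hbb-bs by 2.27 ± 0.28 (adjusted p = 0.00175). The troponin gene Tnnc2, of fast muscle, was at 0 in untreated marrow and 18.3 ± 9.79 CPM with both agents, at least 66.4-fold higher (adjusted p = 0.0055). Kbtbd11 fell by 5.88 ± 0.60 (adjusted p = 0.000903). For each of these genes both combined libraries lay beyond both untreated libraries.

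The interferon list fell with 9 of 17 lower and 14 adjusted over the list alone (median −1.63, adjusted p = 4.6e-11, and adjusted p = 0.256 with an estimated correlation). Several lists fell in the edgeR scaling but had positive medians on the TPM scale, where the median of all genes was 0.90 (−0.01 in the edgeR fit). The monocyte list had 11 of 18 lower, and 15 lower and 1 higher adjusted over the list alone (median −0.84, but 0.35 on the TPM scale; adjusted p = 5.2e-09). Given in the same way, the next were erythroid (8 of 15 lower, 9 alone; −0.99, but 0.22 on the TPM scale; 8.6e-06) and dendritic (6 of 14, 7 alone; −0.78, but 0.37 on the TPM scale; 1.9e-05). Then came mature neutrophil (5 of 12, 5 alone; −0.44, but 0.76 on the TPM scale; 0.000257) and secondary granule (5 of 15, 7 lower and 1 higher alone; −0.56, but 0.73 on the TPM scale; 0.00111). Last were mast cell (2 of 11, 3 alone; −0.56, but 0.56 on the TPM scale; 0.0172) and T and NK lists (3 lower and 1 higher of 16, 5 and 1 alone; −0.60, but 0.53 on the TPM scale; 0.0422). With an estimated correlation these had adjusted p = 0.178, 0.288, 0.288, 0.288, 0.256, 0.256 and 0.329. Relative to all genes the TPM medians were −0.55, −0.68, −0.53, −0.14, −0.18, −0.35 and −0.37. The megakaryocyte list rose with 7 of 12 adjusted over the list alone and no member over all genes (median 2.24, adjusted p = 6.4e-07, and adjusted p = 0.329 with an estimated correlation). So did the endothelial list (median 1.07, adjusted p = 0.0170, and adjusted p = 0.595 with an estimated correlation). The primary granule list did not pass (median 0.26, adjusted p = 0.137). Mpo (0.62 ± 0.21, adjusted p = 0.104) and Ctsk (−0.38 ± 0.51, adjusted p = 0.681) were not called. The respiratory chain gene mt-Co2 rose by 1.76 ± 0.24 (adjusted p = 0.00347). Csf1r changed by −0.66 ± 0.17 (adjusted p = 0.0506; 0.0353 without untreated replicate 1).

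The combination called 1137 genes against untreated, 467 higher and 670 lower, and 3793 higher and 123 lower on the TPM scale. Without combined replicate 1 it called 296 and without combined replicate 3 417. It called, without untreated replicate 1 683 and without untreated replicate 2 676.

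**Figure D1:**
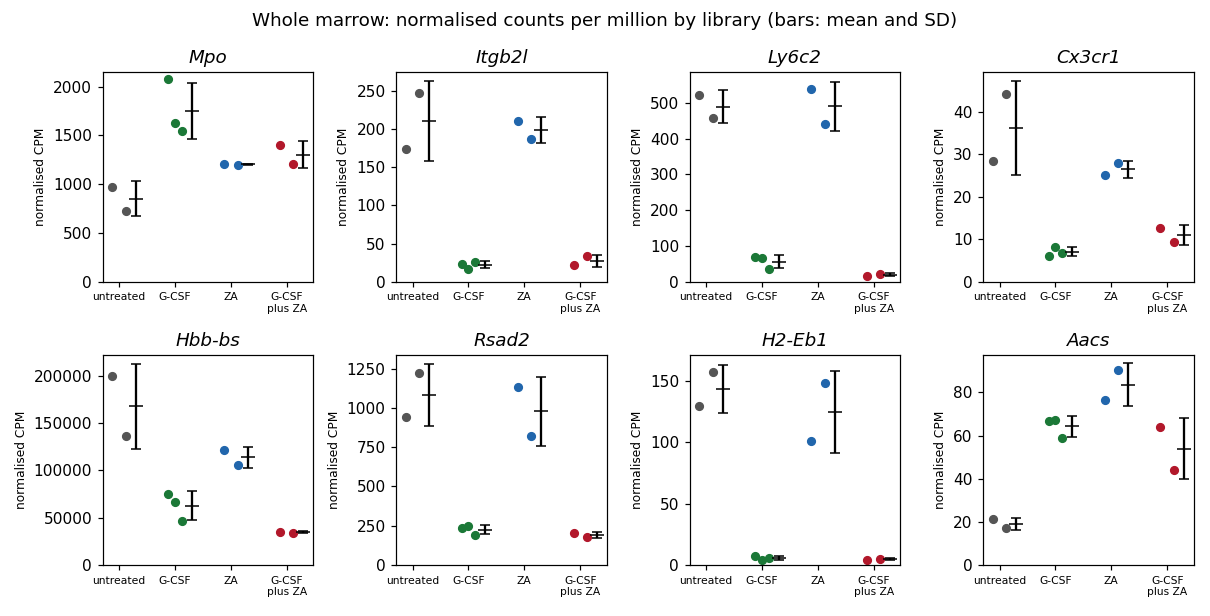
TMM-scaled CPM of 8 genes in each of the 9 whole marrow libraries, by treatment, with bars for the mean and SD. Ly6c2, Rsad2, Itgb2l and H2-Eb1 are low in both groups given G-CSF, and Aacs is lowest in the untreated group.

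Adding ZA to G-CSF was examined against G-CSF alone, which asks what the bisphosphonate changes in marrow under the cytokine. Granule genes were lower with the combination. All 10 primary granule changes were negative and 6 passed adjusted over the list alone (median −0.52, adjusted p = 6.1e-06, and adjusted p = 0.290 with an estimated correlation). Likewise 7 of the 15 secondary granule genes passed so (median −0.36, adjusted p = 4.8e-06, and adjusted p = 0.184 with an estimated correlation). Interferon genes were lower, 7 of 17 adjusted over the list alone (median −0.83, adjusted p = 4.1e-06, and adjusted p = 0.342 with an estimated correlation). So were T and NK genes, 4 of 16 (median −0.65, adjusted p = 2.7e-05, and adjusted p = 0.184 with an estimated correlation). Mitochondrially encoded genes were higher, 7 of 13 (median 0.56, adjusted p = 1.8e-06, and adjusted p = 0.342 with an estimated correlation). So were B lineage genes, 3 of 16 (median 0.23, adjusted p = 0.000895, and adjusted p = 0.342 with an estimated correlation).

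Single genes moved less clearly. The mature neutrophil list fell with 5 of 12 lower adjusted over the list alone (median −0.36, adjusted p = 0.000473, and adjusted p = 0.342 with an estimated correlation). The monocyte list fell (median −0.18, but 0.15 on the TPM scale, −0.11 relative to the median of all genes there, 0.26; adjusted p = 0.0268, and adjusted p = 0.397 with an estimated correlation). So did the mevalonate list (−0.23, but 0.10 on the TPM scale; adjusted p = 0.0243, and adjusted p = 0.517 with an estimated correlation). In 7 genes both combined libraries lay on 1 side of the 3 G-CSF libraries, but none of the 7 passed. Higher were Nckipsd, an adaptor of the actin machinery (2.38 ± 0.28, adjusted p = 0.0651), the skeletal actin gene Acta1 (3.23 ± 0.39, adjusted p = 0.0651) and Cd22 (1.65 ± 0.28, adjusted p = 0.145). Lower were Gzma (−1.96 ± 0.29, adjusted p = 0.0956), Ctsk (−2.78 ± 0.45, adjusted p = 0.127), Oas1a (−1.78 ± 0.30, adjusted p = 0.141) and Spp1 (−1.78 ± 0.36, adjusted p = 0.214). Ctsk was at 2.76 CPM with both agents and 18.9 ± 3.31 with G-CSF. Haptoglobin, Hp (−0.60 ± 0.14, adjusted p = 0.258), Mpo (−0.42 ± 0.19, adjusted p = 0.480), Csf1r (−0.03 ± 0.16, adjusted p = 0.973) and Fdps (−0.44 ± 0.18, adjusted p = 0.444) did not pass either.

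The edgeR test called 1 of 14737 genes here, with 1530 at an unadjusted p under 0.05, and DESeq2 called 95 higher and 109 lower. Without the filter on low counts edgeR called 557, and with the replicate number as a block 0. The called gene, the predicted model Gm20431, was at least 75.7-fold higher (adjusted p = 0.0202) but averaged 2.38 CPM, below the naming rule. It was not called without combined replicate 3 (adjusted p = 0.0725), untreated replicate 1 (0.0513) or 2 (0.0653), or G-CSF replicate 2 (0.0858), nor under the block (0.0692) or in a fit of the 2 groups alone (0.0924). Leaving out 1 library gave 18 calls without G-CSF replicate 3, and 7 and 4 without ZA replicates 2 and 3. It gave 3 without combined replicate 1, 2 without G-CSF replicate 1 and 0 without G-CSF replicate 2. Among these, Nckipsd (adjusted p = 0.0398), Gzma (0.0457) and Oas1a (0.0457) passed without G-CSF replicate 3. Acta1 (0.00341) passed without combined replicate 3, and Ctsk without ZA replicate 2 (0.0383) or 3 (0.0423).

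The combination differed from ZA alone in 638 genes, 275 higher and 363 lower (193 and 60 on the TPM scale, where the median of all genes was 0.59). Interferon genes were lower (8 of 17, 13 adjusted over the list alone; median −1.18, adjusted p = 3.8e-11, and adjusted p = 0.250 with an estimated correlation). So were mitochondrially encoded genes (4 of 13, 11 alone; median −0.77, adjusted p = 3.1e-07, and adjusted p = 0.289 with an estimated correlation). The secondary granule list fell (median −0.58, but 0.17 on the TPM scale; adjusted p = 3.8e-08, and adjusted p = 0.163 with an estimated correlation). The megakaryocyte list rose (median 1.45, adjusted p = 3.1e-07, and adjusted p = 0.314 with an estimated correlation). The mature neutrophil, monocyte, erythroid, dendritic and STAT3 lists also fell in the edgeR scaling (medians −0.49, −0.56, −0.68, −0.36 and −0.43). On the TPM scale the medians of these lists were 0.26, 0.18, 0.09, 0.30 and 0.28, positive but under the 0.59 of all genes there. Their adjusted p values were 1.35e-05, 1.2e-05, 1.6e-05, 0.0018 and 0.00255, and with an estimated correlation 0.289, 0.250, 0.289, 0.323 and 0.289. B lineage rose (0.31, adjusted p = 0.0424, and adjusted p = 0.447 with an estimated correlation). The pseudogene Rps3a2, uncertain because of its parent gene, rose by 10.63 ± 0.37 (adjusted p = 1.4e-06). Ifi202b was at least 105-fold higher (adjusted p = 0.00142). Gvin1 and Eps8l1 were at least 282-fold and 169-fold lower (adjusted p = 0.00489 and 0.000283). The count was 251 without combined replicate 1 or 3, 261 without ZA replicate 2 and 417 without G-CSF replicate 2.

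ZA alone differed from G-CSF alone in 746 genes, 441 higher and 305 lower (80 and 169 on the TPM scale, where the median of all genes was −0.32). With ZA, mitochondrially encoded genes were higher (9 of 13, 11 adjusted over the list alone; median 1.33, adjusted p = 5.0e-13). So were interferon genes (7 of 17, 7 alone; 0.75, 3.6e-05) and erythroid genes (2 of 15, 5 alone; 0.54, 0.000309). The megakaryocyte list was lower (median −1.45, adjusted p = 4.3e-07). Each had an adjusted p = 0.444 with an estimated correlation. Vill rose by 8.56 ± 0.68 (adjusted p = 0.000182), Rps3a2 fell by 11.01 ± 0.36 (adjusted p = 5.5e-07) and Ifi202b was at least 53.8-fold lower (adjusted p = 0.00187). The count was 328 without ZA replicate 2, and 441 and 406 without G-CSF replicates 1 and 2.

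The interaction in marrow asks whether the combination departed from the sum of both agents' log2 changes. Gm20431 was the 1 gene called of 14737 (adjusted p = 0.0206; 1738 at an unadjusted p under 0.05; DESeq2 170 higher and 87 lower; edgeR 746 without the filter on low counts). Under the replicate block it had an adjusted p = 0.0593 and 3 genes were called. It was not called without combined replicate 3 (adjusted p = 0.0566), untreated replicate 2 (0.0666), or ZA replicate 2 (0.0993) or 3 (0.0738). Calls numbered 10 without untreated replicate 1, 6 without combined replicate 1, 3 without G-CSF replicate 1 and 0 without either ZA replicate. Primary granule genes stood lower than the sum, 7 of 10 adjusted over the list alone (median −0.79, adjusted p = 2.8e-06, and adjusted p = 0.334 with an estimated correlation). So did secondary granule genes, 5 of 15 (−0.72, adjusted p = 2.9e-06, and adjusted p = 0.277 with an estimated correlation).

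In sorted precursors, the tissue was first compared with whole marrow, which checks what the sort kept. In run 1, 5 precursor libraries of the 3 treatments with marrow were set against 3 marrow libraries. The division described above enters here too. Of the genes off in G-CSF marrow, the 6 with at least 5 TPM in G-CSF precursors had a median of 47.7 TPM there. In the G-CSF marrow library they were at 0 TPM. The treatment term does not remove such genes, so they may be among the calls. Csf1r (ENSMUSG00000024621, chromosome 18, 61100598 to 61132149), the CD115 receptor used for the sort, was higher by 1.76 ± 0.18 (adjusted p = 0.000274), and the chemokine receptor Ccr2 by 2.47 ± 0.19 (adjusted p = 8.0e-05). Irf8 was higher by 2.67 ± 0.34 (adjusted p = 0.000761), F13a1 by 2.76 ± 0.16 (adjusted p = 2.2e-05). So were the progenitor genes Cd34 and Flt3 by 2.501 ± 0.17 (adjusted p = 4.1e-05) and 1.52 ± 0.13 (adjusted p = 0.000103). Tnfrsf11a, the receptor that starts osteoclast formation, was higher by 1.67 ± 0.41 (adjusted p = 0.0139). Hbb-bs fell by 8.35 ± 0.60 (adjusted p = 6.3e-05) and S100a8, a calprotectin subunit of neutrophils, by 6.34 ± 0.15 (adjusted p = 1.6e-06). Ltf fell by 6.73 ± 0.25 (adjusted p = 3.2e-06) and the B cell receptor component Cd79a by 7.00 ± 0.29 (adjusted p = 4.7e-06). For Csf1r and Hbb-bs all sorted libraries of run 1 lay beyond all its marrow libraries. The erythroid list fell in 15 of 15 members (median −8.25, adjusted p = 1.5e-12, and adjusted p = 0.184 with an estimated correlation). So did T and NK in 14 of 14 (−5.79, 1.5e-07 and 0.184) and B lineage in 15 of 16 (−5.72, 3.2e-11 and 0.0721). The monocyte list rose with 12 higher and 2 lower of 18 (1.58, adjusted p = 0.000411, and adjusted p = 0.376 with an estimated correlation). The primary granule list did not pass, with 2 higher and 5 lower of 10 (median −0.29, adjusted p = 0.399). Mpo (0.71 ± 0.25, adjusted p = 0.0536), Elane (0.09 ± 0.17, adjusted p = 0.711) and Nfatc1 (0.18 ± 0.12, adjusted p = 0.259) were not called. Csf3r fell by 1.02 ± 0.17 (adjusted p = 0.00281). In all, 7220 genes were called in run 1, 3409 genes higher and 3811 lower.

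The run 2 libraries as labelled did not show this difference. There edgeR called 0 of 16136 genes (164 at an unadjusted p under 0.05; DESeq2 2), with Csf1r at −0.35 ± 0.54 and Hbb-bs at 2.32 ± 2.67 (adjusted p = 1.00 for both). Haemoglobin genes took 32.5% to 48.9% of the TPM of 5 run 2 libraries labelled precursor: untreated 2 (48.9%), untreated 7 (35.5%), G-CSF 2 (32.5%), ZA 5 (43.9%) and ZA 7 (44.5%). In the libraries labelled whole marrow untreated 2 and G-CSF 2 of run 2 they took 0.230% and 0.135%. Untreated 7, ZA 5 and ZA 7 are in the final comparison, so the library labelled untreated 7 is 1 of its 2 untreated libraries.

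**Figure D2:**
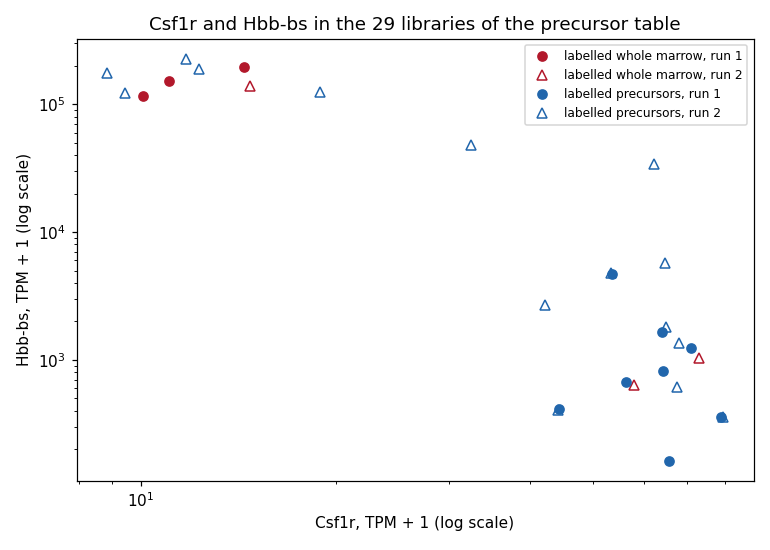
TPM + 1 of Csf1r against Hbb-bs on log axes in the 29 libraries of the precursor table, by labelled tissue and run. In run 1, precursors had 43.3 to 77.9 TPM of Csf1r and marrow 9.05 to 13.4, while Hbb-bs was at 161 to 4672 TPM in precursors and 116788 to 197273 TPM in marrow.

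G-CSF was compared with no treatment in precursors to ask whether it alters the cells that form osteoclasts. In run 1 there was 1 untreated library. Values for run 2 in this and the other treatment comparisons take every precursor library of that run, and those labelled untreated 2 and 7, G-CSF 2, ZA 5 and 7 and combined 3 had a marrow profile. G-CSF 1 of run 2 had 8.39% of its TPM in haemoglobin genes. Combined 1 and 4 of run 2 were both like combined 1 of run 1 (2.09 and 1.62 times counting noise). G-CSF 3 and 5 were both like G-CSF 3 of run 1 (1.98 and 1.69), and ZA 6 and 8 were like each other (2.42). Values for run 2 may thus count 1 sample more than once. Csf1r in run 1 was at 489 ± 36.3 CPM with G-CSF (n = 3) and 501 in the untreated library (n = 1). In the same order Csf3r was at 151 ± 21.9 and 141, Nfatc1 at 70.3 ± 2.41 and 72.8, and Mpo at 3127 ± 337 and 3861. Pooled over both runs, Csf1r changed by 0.56 ± 0.42 (run 1 −0.03 ± 0.11, run 2 1.14 ± 0.59) and Csf3r by 0.01 ± 0.35 (0.10 ± 0.15 and −0.43). Nfatc1 changed by 0.05 ± 0.11 (−0.05 ± 0.12 and −0.08), Tnfrsf11a by 0.72 ± 0.49 (0.13 ± 0.54 and 0.95) and Mpo by 0.26 ± 0.31 (−0.30 ± 0.12 and 1.11). Acp5 changed by −2.93 ± 1.20 (−0.11 ± 0.38 and −2.33) and Ltf by −4.52 ± 1.80 (−0.89 ± 0.65 and −1.87). None of these was called. Chd7, a chromatin remodeller, was among the smallest p values without passing (−1.54 ± 0.31, adjusted p = 0.361; run 1 −0.61 ± 0.18, run 2 −1.40).

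The pooled lists of mature lineages fell. The erythroid list had 15 of 15 lower adjusted over the list alone (median −6.52, adjusted p = 5.9e-09; run 1 −1.21, run 2 −2.49). So did the stromal list with 16 of 21 (−6.01, 2.3e-10; run 1 −0.77, run 2 −2.35) and the megakaryocyte list with 12 of 12 (−5.09, 8.2e-10; run 1 −0.89, run 2 −1.28). The T and NK list fell as well (−4.34, 1.3e-08; run 1 −0.63, run 2 −2.26). Each of these 4 had an adjusted p = 0.309 with an estimated correlation. The library labelled untreated 7, with 35.5% of its TPM in haemoglobin genes, is 1 of the 2 libraries behind the untreated mean. The monocyte list rose (median 0.60, adjusted p = 0.00317, and adjusted p = 0.309 with an estimated correlation; run 1 0.10, run 2 1.02). The osteoclast list did not pass (−0.30, but 0.21 on the TPM scale; adjusted p = 0.894; run 1 0.00, run 2 −0.09). On the TPM scale the median log2 change of all genes was 0.26 here, −0.11 for ZA against untreated, and −0.36 for both the combination and ZA against G-CSF. The edgeR test called 0 of 18954 genes (2479 at an unadjusted p under 0.05; 0 in run 1 alone, with 486; 6 in run 2 alone). DESeq2 called 59 higher and 365 lower. Without untreated replicate 2, which leaves the library labelled untreated 7 alone in its group, edgeR called 676, Chd7 among them (−2.19, adjusted p = 0.0072).

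ZA was compared with no treatment in precursors, where its target enzyme sits in the cell lineage it acts on. Fdps changed by 0.30 ± 0.29 pooled (run 1 −0.05 ± 0.19, run 2 0.92) and Csf1r by 0.12 ± 0.43 (−0.12 ± 0.13 and 0.76). Tnfrsf11a changed by −0.06 ± 0.49 (0.06 ± 0.66 and 0.06) and Nfatc1 by −0.13 ± 0.11 (−0.15 ± 0.14 and −0.22). None was called. In run 1 this sets 1 ZA library against 1 untreated library, and both untreated libraries of run 2 have a marrow profile. The ubiquitin ligase subunit Fbxo40 had 1 of the smallest p values without passing (−3.49 ± 0.68, adjusted p = 1.00; run 1 −3.10, run 2 −2.67). The megakaryocyte list fell (median −1.11, adjusted p = 6.5e-09, and adjusted p = 0.530 with an estimated correlation; run 1 −0.79, run 2 −0.92). So did the stromal list (−1.44, adjusted p = 6.2e-07, and adjusted p = 0.576 with an estimated correlation; run 1 −0.21, run 2 −1.32). The primary granule list rose (0.26, adjusted p = 0.0472, and adjusted p = 0.530 with an estimated correlation; run 1 0.05, run 2 0.29). The libraries labelled untreated 7, ZA 5 and ZA 7, which enter these pooled values, have a marrow profile. In the erythroid list the median was −0.07, the mean 0.04 and the test down (run 1 −0.15, run 2 −0.81). In the B lineage list the median was 0.05 (−0.77 on the TPM scale), the mean 0.01 and the test down (run 1 −0.43, run 2 −0.86). By edgeR 0 genes were called (785 at an unadjusted p under 0.05; 0 in run 1 alone, with 497; 2 in run 2 alone). DESeq2 called 3 higher and 7 lower, and 78 were called by edgeR without untreated replicate 2.

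The combination against no treatment in precursors gave smallest p values for Btnl9, a butyrophilin-like gene (−1.68 ± 0.25, adjusted p = 0.141; run 1 −1.39 ± 0.34, run 2 −1.45). Next were Ifih1, a sensor of viral RNA (−1.16 ± 0.20, adjusted p = 0.266; run 1 −0.76 ± 0.26, run 2 −1.54) and Psph, of serine synthesis (−0.94 ± 0.16, adjusted p = 0.266; run 1 −0.75 ± 0.21, run 2 −0.57). None of these passed. Csf1r changed by 0.53 ± 0.42 (run 1 −0.07 ± 0.11, run 2 1.23), Nfatc1 by 0.02 ± 0.11 (−0.08 ± 0.12 and −0.03) and Mpo by 0.41 ± 0.31 (−0.13 ± 0.12 and 1.20). The interferon list fell (median −0.52, adjusted p = 0.00198; run 1 −0.27, run 2 −1.23). So did the megakaryocyte (−5.42, 1.1e-08; run 1 −1.25, run 2 −2.19) and erythroid lists (−4.63, 1.8e-05; run 1 0.40, run 2 −3.32). Each of the 3 had an adjusted p = 0.397 with an estimated correlation. The library labelled untreated 7, with a marrow profile and 35.5% of its TPM in haemoglobin genes, is 1 of the 2 untreated libraries, and in run 1, which lacks it, the erythroid median was positive. Pooled, edgeR called 0 genes (2438 at an unadjusted p under 0.05; 0 in run 1 alone, with 688; 3 in run 2 alone) and DESeq2 55 higher and 222 lower. Without untreated replicate 2 edgeR called 341, with Btnl9 (adjusted p = 0.0133), Ifih1 (0.0122) and Psph (0.0257) among them.

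The combination against G-CSF alone pooled 5 final precursor libraries in each group, none with a marrow profile. Of these, combined 4 and 5 and G-CSF 4 and 5 differed from combined 1 and 3 and G-CSF 1 and 3 by 1.62 to 2.01 times counting noise. With like libraries counted once edgeR also called 0 genes (877 at an unadjusted p under 0.05). Btnl9 was lowest by p without passing (−1.35 ± 0.20, adjusted p = 0.137; run 1 −1.44 ± 0.26, run 2 −0.65), at 3.20 ± 0.441 CPM with both agents and 8.64 ± 2.47 with G-CSF in run 1 (n = 3 each). Trrap, a scaffold of histone acetyltransferases, changed by 0.43 ± 0.08 (adjusted p = 0.479; run 1 0.40 ± 0.11, run 2 0.39). Csf1r changed by −0.03 ± 0.31 (−0.04 ± 0.08 and 0.09), Nfatc1 by −0.03 ± 0.08 (−0.03 ± 0.08 and 0.04) and Fdps by 0.14 ± 0.21 (0.17 ± 0.11 and 0.02). No list passed pooled. In run 1 the monocyte list was lower (median −0.18, adjusted p = 1.2e-05, and adjusted p = 0.352 with an estimated correlation). So was the interferon list (−0.35, 0.00109 and 0.685), while the erythroid list was higher (1.34, 8.3e-05 and 0.685). In run 2, where the libraries labelled G-CSF 2 and combined 3 had a marrow profile, their medians were −0.16, −0.36 and −0.92. Over both runs edgeR called 0 genes (1162 at an unadjusted p under 0.05; 0 in run 1 alone, with 1306; 0 in run 2 alone, with 687). DESeq2 called 68 higher and 45 lower. By edgeR 336 genes were called without the libraries with a marrow profile, which removes libraries of the other groups only, and 105 in a fit of the 2 groups alone. With like libraries also counted once, the 336 became 0 (1442 at an unadjusted p under 0.05).

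Against ZA alone, the combination lowered Btnl9 by 1.74 ± 0.21 on the log2 scale, the 1 gene that edgeR called in a precursor treatment comparison pooled over all final libraries with a run term (adjusted p = 0.0135; 3280 at an unadjusted p under 0.05; DESeq2 348 higher and 814 lower). In run 1 Btnl9 was at 11.7 CPM with ZA (n = 1). Its change was −1.88 ± 0.33 in run 1 (adjusted p = 0.825) and −1.24 in run 2, where neither passed. Its call was lost without combined replicate 2 (adjusted p = 0.0616), 3 (0.0601), 4 (0.120) or 5 (0.0826), or ZA replicate 3 (0.208). It was also lost with like libraries counted once (−1.68, adjusted p = 0.993), with the replicate number as a block (−1.60, 0.243) and in a fit of the 2 groups alone (−1.77, 0.230). Without the libraries with a marrow profile edgeR called 231 genes here, and 0 when like libraries were also counted once (809 at an unadjusted p under 0.05). Over the other settings for Btnl9 adjusted p ran from 7.6e-11 to 0.993. ZA 6 and ZA 8 differed from ZA 3 by 2.32 and 1.79 times counting noise and ZA 5 and ZA 7 had a marrow profile, so 1 distinct precursor library stands for ZA once these are set aside. The cilium gene Cfap45 (−2.67 ± 0.40, adjusted p = 0.0807; run 1 −2.45 ± 0.45, run 2 −1.47) passed without untreated replicate 2 (0.00699) or 7 (0.00669). Zmynd11, a chromatin reader, changed by 0.65 ± 0.11 (adjusted p = 0.0871; run 1 0.62 ± 0.12, run 2 0.54). Interferon genes were lower, 8 of 17 adjusted over the list alone (median −0.56, adjusted p = 0.00377, and adjusted p = 0.646 with an estimated correlation; run 1 −0.23, run 2 −0.72).

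ZA against G-CSF in precursors called 0 genes with edgeR (2551 at an unadjusted p under 0.05; DESeq2 685 higher and 182 lower; edgeR 206 without the libraries with a marrow profile, and 0 with like libraries also counted once, with 710). The Hippo kinase Lats2 was at −1.35 ± 0.24 (adjusted p = 0.330; run 1 −1.31 ± 0.56, run 2 −0.99) and the mTORC1 regulator Nprl2 at −0.70 ± 0.13 (adjusted p = 0.330; run 1 −0.67 ± 0.22, run 2 −0.50). The erythroid list was higher with ZA, 15 of 15 adjusted over the list alone (median 6.16, adjusted p = 2.9e-06, and adjusted p = 0.505 with an estimated correlation; run 1 1.504, run 2 1.62). The libraries labelled ZA 5 and ZA 7, with 43.9% and 44.5% of TPM in haemoglobin genes, are among the 5 given ZA. The interaction called 0 genes with edgeR (1083 at an unadjusted p under 0.05; DESeq2 22 higher and 21 lower; 59 with edgeR without untreated replicate 2). Eprs, a transfer RNA synthetase, was at 0.69 ± 0.13 (adjusted p = 0.606; run 1 0.64, run 2 0.21) and Cfap45 at −3.17 ± 0.64 (adjusted p = 0.606; run 1 −4.15, run 2 −1.54).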

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

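The tests of exchanged labels, of mixed RNA, of repeated libraries and of separate mice were chosen after the results were seen; those of the genes on or off in G-CSF marrow and the other splits were planned. Among the 69 groups of samples tested for an outlying member 2 were found, and chance alone marks about 1 in 20. In precursors, the mean log2 CPM of the STAT3 list was 5.192 in G-CSF replicate 2, above the other 4 libraries at 4.671 to 4.729. The mean of the mitochondrially encoded list was 9.488 in combined replicate 2, below the others at 9.619 to 9.659. In both groups the other 4 libraries form 2 like pairs, so each value stands against 2 distinct samples.

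In marrow the interaction of G-CSF and ZA passed its test for 1 gene and 9 lists, each a difference between the effect of ZA with and without G-CSF. Gm20431 had a log2 interaction of 10.78, a fitted value that depends on the prior count since G-CSF marrow held almost no counts of it. The list medians were −0.7947 for primary granule, −0.7178 for secondary granule, −0.4989 for mature neutrophil, −1.13 for stromal niche, 0.5313 for B lineage, 0.6647 for plasma cell, −0.8989 for interferon response, −0.2804 for STAT3 and −0.2909 for mitochondrially encoded genes. With an estimated correlation their adjusted p values were 0.334, 0.277, 0.650, 0.742, 0.480, 0.552, 0.650, 0.619 and 0.742, so none passed that way.

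In the repeat run of precursor samples, which the pooled treatment comparisons do not use but the values for run 2 alone do, Eno1b stood above the 0.147 TPM of the untreated precursor library of run 1. It was at 54.49 TPM in G-CSF 2, 31.32 in combined 3, 13.35 in G-CSF 1, 2.142 in combined 1 and 0.6065 in G-CSF 3. Modelled as a mixture of its own run 1 library and the G-CSF marrow library, the library labelled G-CSF 2 took 99.7% from marrow and combined 3 64.1%. In the same way G-CSF 1 took 29.6%, combined 1 3.34% and G-CSF 3 1.70%. These shares depend on the marrow library used. With the untreated one combined 3 took 7.07% and G-CSF 1 2.13%, with larger residuals.

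The run 2 libraries labelled untreated 2 and G-CSF 2 had the profile of the other tissue, both in marrow and in precursors. The highest Hbb-bs level of the 2 libraries labelled marrow was 1037 TPM, far under the 116788 TPM of the lowest run 1 marrow library. TPM is a share, which added RNA dilutes, so this argues only against a large part of marrow RNA in those 2. The test did not cover the 2 libraries labelled precursor. Modelled as mixtures of their own run 1 library and run 1 marrow of their treatment, they took 93.1% (untreated 2) and 99.7% (G-CSF 2) from marrow. All 4 libraries were nearest to the run 1 library of the other tissue with their treatment and number, so an exchange of labels between tissues in run 2 may account for them. Distances to those libraries were 1.65, 1.63, 2.42 and 4.68 times counting noise, against 60.1 to 102 to the library of their own label. The 4.68 is of the library labelled precursor untreated 2. It lies above the bound set for the same library sequenced again. It is also within the 3.96 to 11.9 of whole marrow pairs of the same group. Run 1 holds no other untreated marrow library, so for untreated 2 this match cannot tell the same sample from another untreated marrow. No biological explanation was tested, and untreated 7, ZA 5 and ZA 7 have no run 1 library under their own label to compare.

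In marrow, 61 genes were on or off in all 5 libraries of both G-CSF groups against the other 4. The highest count in any other of the 126 splits was 37 and the median 2. Of those 37 genes, 32 were ribosomal RNA genes, on in untreated 1 and 2, ZA 2 and 3 and G-CSF 3. That split also parts combined marrow from untreated and ZA marrow, so its count is not a measure of chance alone. Its cause was not tested. Reads assigned differently among near-identical gene copies may account for part of the 61, since 8 of them were protein-coding and 32 of the on genes and 2 of the off genes were pseudogenes. Mice of another genetic background could not be told apart from treatment, because background and group coincide and 1 of the 3 genes named in advance met the prediction: Nnt, deleted in part in C57BL/6J, was at 7.49 to 13.2 TPM in the G-CSF groups and 1.46 to 3.89 in the others, Ly6a overlapped, and Klra8 was at most 0.557 TPM, too near the floor to count. Genes chosen after their values were seen, which differ between mouse strains, followed the same division: the pseudogene form of H2-Ea at 1.33 to 5.01 TPM against 0, and Ighg2c at 0 to 0.0914 against 1.21 to 14.3. Whether G-CSF itself shuts genes off was not decided by the test. The median marrow to precursor ratio of the 6 usable genes was 0, and the bound, the 5th percentile of 221 reference genes, was also 0. In run 1 these 6 genes had a median of 47.7 TPM in G-CSF precursors and 0 TPM in the G-CSF marrow library. The median ratio of the reference genes was 0.0828. The marrow side rests on 1 library, so this stays open, as does treatment as a biological cause.

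Precursor libraries under different replicate numbers of 1 group were alike, in 7 pairs at 1.625 to 2.417 times counting noise. All 6 final run 2 libraries without a marrow profile lay within 2.318 times counting noise of a run 1 library of their treatment, under the 3.775 of the nearest among the 6 run 1 pairs within G-CSF or the combination, which argues against separate mice that differ little. The same library sequenced again under a new number may account for them, though of 9 repeats labelled as such only 2 were so close (1.98 and 2.09), while 3 were at 4.77, 10.7 and 15.6 and 4 were those with the other tissue's profile. The bound of 2.5 was set after these values were seen, and no biological explanation was tested. Counted once, the 17 final libraries come to 11.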

How the results depend on the processing

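The tests of treatments in run 1 alone, with like libraries counted once, without libraries with a marrow profile, and the run comparison without the samples labelled untreated 2 and G-CSF 2 were chosen after the results were seen. With DESeq2 size factors all 135 gene results named in the text kept their side of the threshold, and with the DESeq2 Wald test 110 did and 25 became called. Results called in either setting kept their direction in both. Of those tested on the TPM scale, 85 kept their side, 17 lost the call and 3 gained it. There 1 called result reversed, Csf1r in G-CSF marrow at 0.19, under the median of all genes on that scale. Changes of sign in results called in neither setting were not counted. Leaving out each library in turn, 50 of the 59 called gene results stayed called every time, 9 lost the call without at least 1, and 12 of the 76 others were called without at least 1. A group left with 1 library is assumed to vary like the others. Causes were not tested unless given.

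Calls without the filter on low counts, which tests more genes, numbered 3206 for G-CSF, 634 for ZA and 2540 for the combination against untreated marrow, 557 for the combination against G-CSF, 1587 against ZA, 1732 for ZA against G-CSF and 746 for the interaction. By the DESeq2 Wald test they were 139 (ZA), 1758 (combination), 204 (combination against G-CSF), 1024 (against ZA), 1135 (ZA against G-CSF) and 257 (interaction). On the TPM scale they were 22, 3916, 20, 253, 249 and 10 in that order. In a fit of the compared groups alone they were 2 for ZA, 748 for the combination against untreated and 5 for the combination against G-CSF. Leaving out each library gave 836 to 1706 for G-CSF, 0 to 23 for ZA, 296 to 1353 for the combination, 0 to 18 for the combination against G-CSF, 251 to 713 against ZA, 328 to 836 for ZA against G-CSF and 0 to 10 for the interaction.

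The replicate number as a block gave 0 calls for ZA and 481 for the combination against untreated marrow, 0 for the combination against G-CSF, 387 against ZA and 3 for the interaction, and 0 in precursors for the combination against ZA; it moved no other count by more than 1.5 times (1361 for G-CSF against untreated marrow). The pairing check found that the numbers do not pair the samples: 1 of 9 same-number pairs in marrow and 2 of 12 in precursors had deviations correlated over 0.1 (median 0.0231 and 0.0241). Under the block 7 of 59 called gene results and 23 of 122 list calls were lost. In precursors given ZA the erythroid median was 1.82 and that of T and NK cells 1.165 under the block, both reversed.

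In precursors the DESeq2 Wald test gave 424 calls for G-CSF, 10 for ZA and 277 for the combination against untreated, 113 for the combination against G-CSF, 1162 against ZA, 867 for ZA against G-CSF and 43 for the interaction; in run 1 alone it gave 13, 19, 23, 91, 43, 28 and 30. On the TPM scale there were 2, 2, 1, 2, 5, 9 and 4, and without libraries with a marrow profile 1, 1, 2, 336, 231, 206 and 3. Run 2 alone gave 6, 2 and 3 against untreated, 0 for the combination against ZA and 1 for the interaction. The groups alone gave 1 for ZA against untreated, 105 for the combination against G-CSF and 0 against ZA. Summed runs gave 1 for the combination against untreated. The random block gave 4 for the combination against G-CSF and 6 against ZA. The combination against ZA had 4 without a run term and 0 in run 1 alone, with like libraries counted once, and with both changes. Leaving out each library gave 0 to 676, 0 to 78, 0 to 341, 0 to 0, 0 to 2, 0 to 0 and 0 to 59 in the first order.

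Precursors against marrow had 2 calls by DESeq2, 0 to 0 without each library and 7220 in run 1 libraries, where run 2 labels do not enter. There, of the genes named in the text and the lists called in run 2, the reversed values that were called in run 1 were Csf1r 1.76, Ccr2 2.47, Irf8 2.67, F13a1 2.76, Cd34 2.501, Flt3 1.52, Tnfrsf11a 1.67, Csf3r −1.02, Hbb-bs −8.35, Ltf −6.73, S100a8 −6.34 and Cd79a −7.00, and for lists secondary granule −6.20, mature neutrophil −5.21, stromal −5.63, erythroid −8.25, B lineage −5.72, T and NK −5.79, mast cell −4.35 and megakaryocyte −5.64. Mpo and Elane also changed sign but were called in neither run. Run 2 against run 1 had 51 calls by DESeq2, 39 in the 6 precursor samples alone, 1 without untreated 2 and G-CSF 2, and 0 to 0 without each sample. With an estimated correlation all 130 list calls of the treatment and tissue comparisons were lost, as were the 7 of run 2 against run 1. It passed no list in any comparison or setting. That includes precursors against marrow in run 1, where fry passed 20 of 22. It therefore does not tell stronger lists from weaker ones here. By fry, of 22 lists in marrow, 7 passed for G-CSF, 0 for ZA and 7 for the combination against untreated. For the combination 2 passed against G-CSF and 7 against ZA, while 5 passed for ZA against G-CSF and 1 for the interaction. In precursors fry passed at most 1 list in any pooled treatment comparison. Depth limits genes near 0.186 to 0.481 CPM in marrow, where a count of 0 allows 3.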

Other observations

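The run 1 tissue comparison, the run comparison and the splits of samples were planned before the data were seen. The shares below were not tested. Prtn3 was called for G-CSF against untreated marrow, as given above, and its other levels are given without a test. Sorted precursors of run 1 also differed from marrow in lineages not yet described. The mature neutrophil list fell in 10 of 12 members, with 2 higher (median log2 change −5.21, adjusted p = 8.0e-06, and adjusted p = 0.0795 with an estimated correlation). In the same order of values, secondary granule genes fell in 14 of 15 (−6.20, 1.9e-11 and 0.163) and mast cell, basophil and eosinophil genes in 11 of 11 (−4.35, 1.3e-08 and 0.0795). Megakaryocyte genes fell in 12 of 12 (−5.64, 1.8e-06 and 0.363) and stromal niche genes in 14 of 16, with 1 higher (−5.63, 6.1e-06 and 0.240). None of these lists passed with an estimated correlation. By fry each of them passed (fry adjusted p = 1.0e-05, 3.0e-05, 3.0e-05, 0.0035 and 0.00084 in the order given). The primary granule gene Prtn3 was at 686 ± 23.5 CPM in G-CSF marrow, 434 ± 51.9 with both agents and 438 ± 10.7 with ZA, against 338 ± 94.7 in untreated marrow. The haemoglobin share of TPM in marrow was 24.8% and 40.3% in untreated libraries, 27.7% to 29.7% with G-CSF, 35.5% and 32.5% with ZA, and 23.5% and 22.0% with both. The 24.8% is of untreated replicate 1, which had 39.1% of its TPM in small RNA genes. That lowers its other shares, so the untreated range is uncertain. The mitochondrial share was 3.45% to 4.25% with G-CSF and 6.51% and 5.35% with both.

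The whole marrow libraries untreated 2, G-CSF 2 and ZA 2 differed from the run 1 marrow libraries of the precursor table by 0.469, 1.18 and 0.699 times counting noise, so both tables hold the same libraries there. The run 2 library labelled ZA 2 whole marrow had 38.8% of its TPM in haemoglobin genes. Run 2 against run 1 in the 9 samples sequenced in both called 0 of 14175 genes with edgeR (119 at an unadjusted p under 0.05; DESeq2 23 higher and 28 lower). Of 22 lists 7 passed, each higher in run 2. The largest medians were erythroid (3.25, camera adjusted p = 1.3e-05), megakaryocyte (3.05, 1.5e-11) and stromal (2.59, 4.1e-06). The others were endothelial, B lineage, T and NK, and mast cell. Each of these lists had an adjusted p = 0.777 with an estimated correlation. The run 2 libraries with the other tissue's profile enter this comparison.

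Other splits of the same libraries into groups of the same sizes show how often chance gives as many calls. For precursors against marrow in run 1, the real split alone, 1 of 56, gave as many (7220 calls, highest other 34). This is the smallest share these splits can give, so chance is unlikely but not excluded. For the combination against ZA in precursors chance is not unlikely, since 4 of 30 splits drawn from 126 gave as many calls (1, highest other 2228). In the other 4 comparisons the real count was 0, which every split reaches, so their 30 of 30 splits say nothing about chance. The highest other counts there were 0 for the combination against G-CSF and 1920 for ZA against G-CSF in precursors, 1 for precursors against marrow as labelled in run 2, and 2649 for run 2 against run 1. The splits with 1920, 2228 and 2649 calls point to a structure of the samples.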
